A study of Mus musculus with 8 samples.

How the data were processed

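Chromatin immunoprecipitation with an antibody against the transcription factor GATA2, followed by sequencing (ChIP-seq), was done in 2 mouse cell lines that are used as models of mesenchymal precursor cells. 3T3-L1 is a fibroblast line committed to the fat cell lineage, and C3H10T1/2 is an embryonic fibroblast line that can be turned into fat, bone, cartilage or muscle cells. The labels name 8 libraries in 4 groups of 2: a GATA2 ChIP group and an input group for each line. Per the labels' protocols, DNA from separate immunoprecipitations was pooled before a library was made from it, so the libraries of a group may differ less than separate cultures would.

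What was analysed is 1 deposited peak list per cell line. Each list gives the chromosome, start and end of every peak in the authors' coordinates and holds no score, height, fold or p column, so the values analysed are positions in bp. Per the submitters' processing notes the genome build was mm10 and the tools were CASAVA 1.8, Bowtie2, SAMtools, bedtools and MACS2, with no role, order or setting given. How the authors combined the libraries of a line, how input was used, which threshold made a peak and what was removed from the lists before they were deposited is not given in the sources used here. Such choices set the number and width of peaks in each list. The read depth behind the lists is unknown, and a different depth or background in the lines would change which weak sites were called. With 1 list per line there is no replicate value, so no difference between the lines could be set against the spread between cultures. All p-values and intervals below cover counting error over peaks or genes only. Expression profiles that the series title mentions were not analysed here.

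Positions are printed counted from 1. Genes were taken from the RefSeq gene table of GRCm38.p6, which is the mm10 assembly, and 21631 protein-coding genes were used. The table gives each gene's lower and higher coordinate without strand or exons. Tests planned on gene starts were therefore run on the distance from a peak's centre to the nearer of the gene's boundaries, either of which can be the start. Exon, intron and UTR positions are not given for the same reason. Planned searches for the GATA motif and other motifs needed a genome sequence, and planned tests on peak scores needed a score column, so neither was run.

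A peak was called shared when it overlapped a peak of the other list by at least 1 bp. The number of shared C3H10T1/2 peaks was compared with 10000 random placements of that list along its own chromosomes, each peak keeping its width, in a one-sided Monte Carlo test. The shares of peaks with centres within 1 kb of a gene boundary and inside a gene body were compared with 10000 random placements in the same way. The boundary test was planned as one-sided. The gene body test was added after seeing the data, and both one-sided p-values were computed for it, each read against 0.025. Shares were compared between classes of peaks with two-sided Fisher's exact tests. The widths of shared and unshared peaks were compared with a two-sided permutation test of mean ranks with 100000 resamples. Intervals are 95% exact Clopper-Pearson intervals.

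Gene groups were 16 lists fixed before the data were examined: GATA factors and cofactors, blood and endothelial GATA2 targets, adipogenesis, osteogenesis, chondrogenesis, myogenesis, BMP and TGF-beta signalling, Wnt signalling, Notch and Hedgehog signalling, extracellular matrix, actin cytoskeleton and YAP targets, AP-1 and immediate early genes, inflammatory mediators, mesenchymal precursor markers, and cytosolic ribosomal proteins and neuronal synapse genes as controls. In the actin list 32 of 34 symbols matched the gene table, because 2 genes were listed under an older and a newer symbol, and every symbol of the other lists matched. The number of a list's genes with a peak centre within 100 kb of a boundary was compared with 10000 random gene lists of the same size, matched in 10 classes on the number of genes within 100 kb. This is a one-sided permutation test of list membership within those classes. Its p-values were adjusted by the Benjamini-Hochberg method over the 32 tests of a setting, and a list was called at an adjusted p under 0.05. Whether the genes of a list divided between the lines otherwise than other genes was tested with Fisher's exact test on genes with a peak in one line alone, adjusted over the 16 lists.

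Other settings fixed before the data were examined were an overlap of at least 50% of both peaks, peak centres within 1 kb, circular shifts of a list, peaks of at least the median width in place of a stricter threshold, a boundary window of 5 kb, gene windows of 10 kb or the nearest gene alone, and random lists matched on gene length. Further settings were chosen after seeing the data. The first left out dense blocks, defined as runs of at least 8 peaks of one list with gaps of at most 20000 bp. The others moved each peak by 10 to 100 kb to either side, counted peaks inside a gene or within 10 kb of it, matched random lists on gene density with length or on window length, and counted neighbouring genes of a list once. Matching on length was run in the 100 kb window alone. Counts by nearest gene and inside genes or within 10 kb can rise with gene length and had no length-matched test. Genes were named by a rule fixed before the data were examined: the 10 genes with the most peaks within 100 kb in each list, the genes at the 10 shared peaks nearest a gene boundary, the listed genes with a peak inside or within 10 kb (up to 20 in both lines and up to 10 in each line alone, by distance to a boundary), and Gata1 to Gata6, Zfpm1, Zfpm2, Pparg, Cebpa, Runx2 and Sp7. The 10 genes with the most peaks outside dense blocks in each list, and any other listed gene named as having a peak, were chosen after their values were seen. The result for 1 listed gene is not reported here.

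The computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. They were tested on simulated data first. In 200 simulations of each kind, the overlap test called 1.5% of unrelated lists and 100% of lists with 30 planted common sites. The gene list test, on lists of 30 genes out of 21631, called 1% of lists with no effect, 57% of lists with a 2-fold excess and 97% of lists with a 3-fold excess at an unadjusted p under 0.05. Simulated peaks were scattered evenly and simulated genes drawn singly, much as the tests draw chance. These rates therefore need not hold for clustered peaks or for lists with neighbouring genes.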

Results

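Sites bound by GATA2, a zinc finger transcription factor that keeps precursor cells from maturing in blood and in fat, were mapped in 3T3-L1 and C3H10T1/2 cells. The labels name 2 ChIP and 2 input libraries per line, and 1 list of peaks was analysed for each line. The 3T3-L1 list held 2445 peaks with a median width of 144 bp (range 50 to 3323), covering 415 kb. The C3H10T1/2 list held 1557 peaks with a median width of 184 bp (range 95 to 1705), covering 318 kb. Both lists covered chromosomes 1 to 19 and X. Because each line is represented by a single list, the difference in number has no replicate check, and the depth behind it is unknown. All coordinates are mm10.

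The block with the most peaks in either list, though not the densest, lay on chromosome 10 in 3T3-L1. A block of 376 peaks ran over 413 kb from 117377462 to 117790202 and covered Mdm2, which encodes the ubiquitin ligase that degrades p53. The body of Mdm2 (117688875 to 117710758) held 33 peaks, that of the neighbouring carboxypeptidase gene Cpm (117629500 to 117687352) held 52, that of the nuclear pore gene Nup107 (117750621 to 117792736) held 42 and that of Slc35e3 (117733678 to 117746358) held 14. A block of 8 peaks from 117281251 to 117287454 lay at the lysozyme genes Lyz2 and Lyz1, and a block of 60 peaks from 107213417 to 107256721 lay between Acss3 and Lin7a. These 3 blocks held 444 of the 2445 peaks of 3T3-L1, at 1136 to 1728 times the density of the rest of the list, and no C3H10T1/2 peak. All 10 genes with the most 3T3-L1 peaks within 100 kb lay at these blocks: Cpm, Mdm2, Slc35e3, Nup107, Rap1b, Cpsf6, Lin7a, Lyz1, Acss3 and Lyz2, with 272 peaks at Cpm and 14 at Lyz2. Chromosome 10 held 23.5% of the 3T3-L1 peaks and 6.29% of the C3H10T1/2 peaks (two-sided Fisher's exact test adjusted over 20 chromosomes, p = 1.86e-49), and 6.53% and 6.40% once dense blocks were left out (adjusted p = 0.993).

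C3H10T1/2 had 1 block of this kind, with 20 peaks from 3184453 to 3199962 on chromosome 11 in the body of Sfi1, which encodes a centrosomal protein. The 3T3-L1 list had 1 peak there. Sfi1, Gm51877, Eif4enif1 and Drg1 had all 20 peaks within 100 kb, and Patz1 had 12. On chromosome 17, 10 peaks of 3T3-L1 and 5 of C3H10T1/2 lay between 39843356 and 39848806, over an annotated pseudogene of the 18S ribosomal RNA, and all 10 overlapped a C3H10T1/2 peak. Whether the peaks of the blocks on chromosomes 11 and 17 mark GATA2 binding was not tested. Those that overlap are counted among the shared peaks below unless dense blocks are left out. Leaving out the 5 blocks removed 455 peaks (18.6%) from the 3T3-L1 list and 25 (1.61%) from the C3H10T1/2 list.

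**Figure D1:**
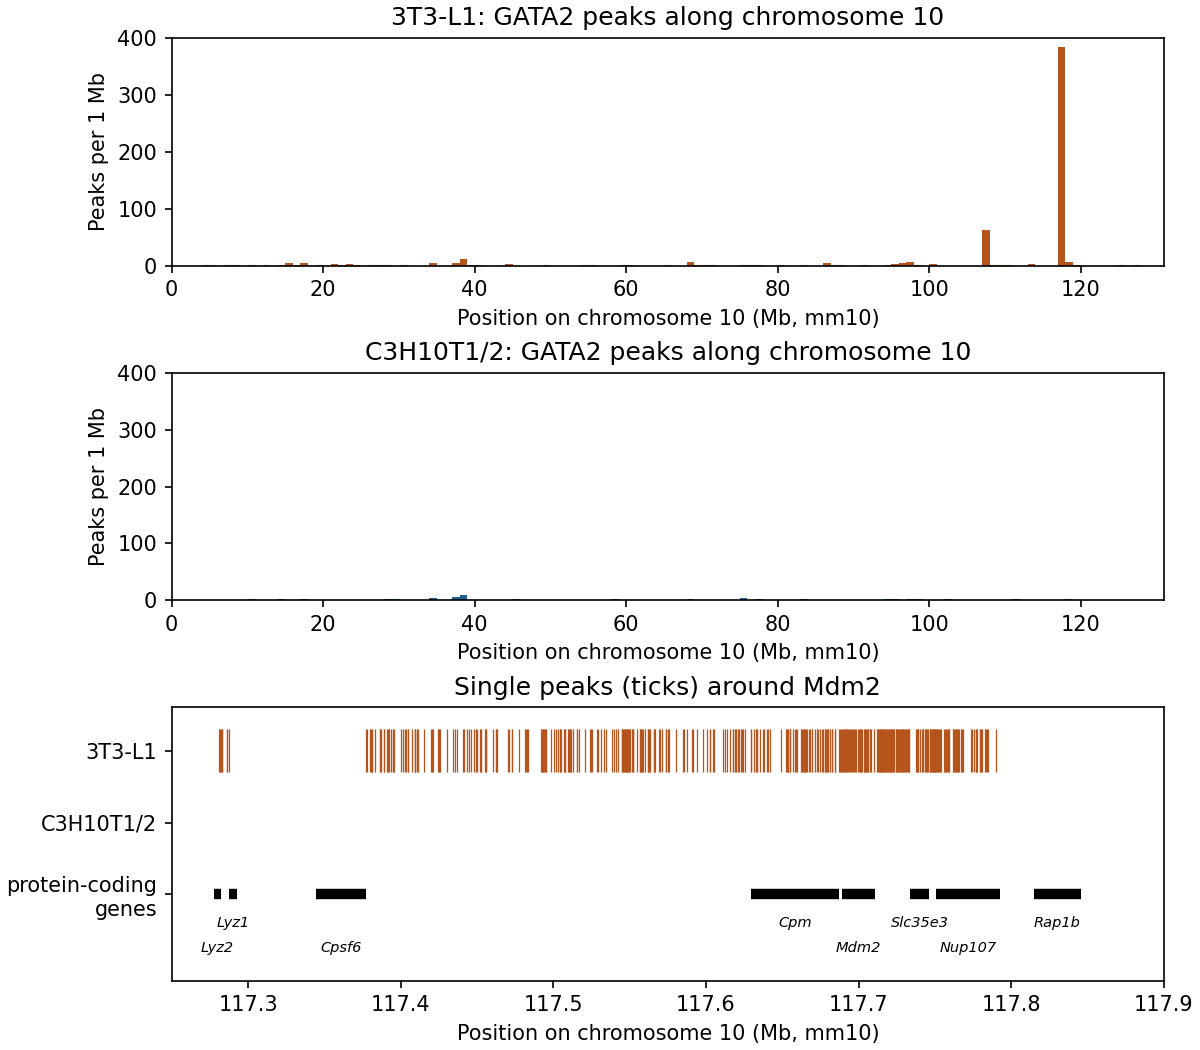
Number of GATA2 peaks per 1 Mb along chromosome 10 (position in Mb, mm10) in 3T3-L1 (top) and C3H10T1/2 (middle), and single peaks as ticks above the protein-coding genes around Mdm2 (bottom). The 376 peaks of the largest 3T3-L1 block run from left of Cpm to Nup107, and the C3H10T1/2 row is empty there.

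Outside these blocks, some genes had many peaks in one list and others in both. Cwc22, a splicing factor gene on chromosome 2 (77881159 to 77946356), had 13 peaks of 3T3-L1 within 100 kb and 0 of C3H10T1/2. The alcohol dehydrogenase gene Adh6b on chromosome 3 had 6 and 0. A cluster of chemokine genes on chromosome 5 that includes Cxcl5 (90759298 to 90761625), Ppbp, Pf4, Cxcl3 and Cxcl15 was dense in both lines, with 7 peaks of 3T3-L1 and 6 of C3H10T1/2 within 100 kb of each of these genes. Ccdc34 on chromosome 2 had 3 and 6 peaks.

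The first comparison asked how many sites the lines had in common. Of the 2445 peaks of 3T3-L1, 548 (22.4%, interval 20.8 to 24.1) overlapped a C3H10T1/2 peak, and 540 of the 1557 C3H10T1/2 peaks (34.7%, 32.3 to 37.1) overlapped a 3T3-L1 peak. Random placement of the C3H10T1/2 peaks gave a mean of 0.631 overlapping peaks and at most 5 in 10000 draws (one-sided p = 0.0001 for n = 1557 peaks, the smallest these draws can give). The other 1897 peaks of 3T3-L1 and 1017 of C3H10T1/2 were in one list alone. Counting shared sites, 57.5% of C3H10T1/2 peaks had a 3T3-L1 peak within 100 kb, where random placement gave 13.0%. At the level of genes, 857 had a 3T3-L1 peak in the body or within 10 kb, 788 had a C3H10T1/2 peak and 364 had both, against 31.2 for independent lists of these sizes. That expectation gives every gene the same chance of a peak. Since the window grows with gene length, it is likely too low.

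Shared peaks nearest to a gene boundary lay at Irf9, which encodes a subunit of the interferon-activated factor ISGF3, and at Wsb1, Tsn, Tcf3, Ift20, Got1, Galnt15, Ndufa9, Zfp763 and Chek2. At Irf9 (chromosome 14, 55603985 to 55610030) the 3T3-L1 peak ran from 55603900 to 55604078 and the C3H10T1/2 peak from 55603854 to 55604116, so both covered the gene's lower boundary. At Tcf3, which encodes the E proteins E12 and E47 (chromosome 10, 80409541 to 80433976), the peaks at its higher boundary ran from 80433809 to 80434166 and from 80433690 to 80434179. At Chek2, which encodes a DNA damage checkpoint kinase, the peak centres lay 113 bp and 92 bp inside the gene.

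Wider peaks were shared more often in both lines. In 3T3-L1 the shared part rose from 13.1% (10.5 to 16) of the narrowest of 4 equally large width classes to 34.7% (30.9 to 38.6) of the widest class. In C3H10T1/2 it rose from 23.6% (19.5 to 28.1) to 50.1% (45.0 to 55.2). Shared peaks had a median width of 173.5 bp against 136 bp for other 3T3-L1 peaks, and 205 bp against 174 bp in C3H10T1/2 (two-sided permutation p = 1e-05 for each, the smallest that 100000 resamples can give).

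**Figure D2:**
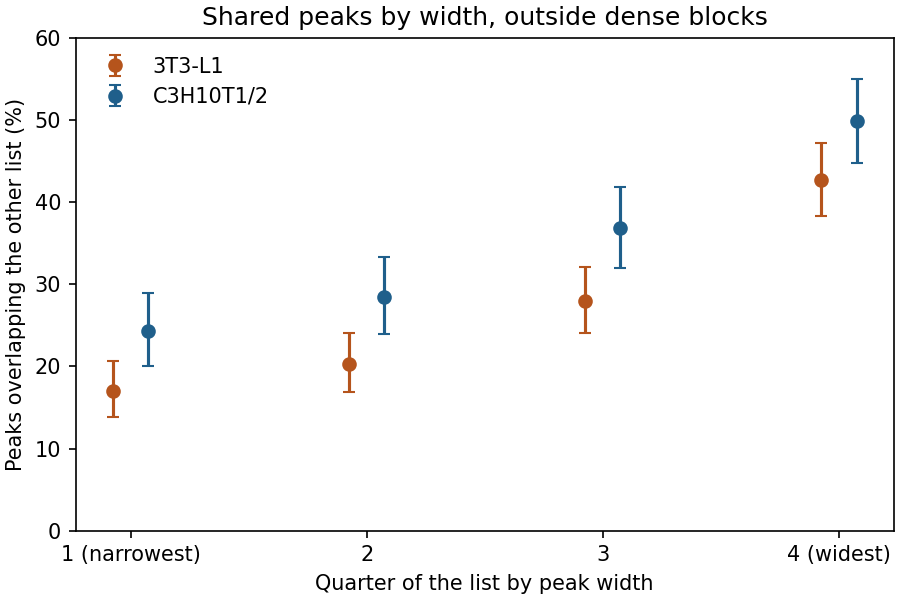
Percent of peaks outside dense blocks that overlap a peak of the other list (y axis), by 4 equally large classes of peak width within each list (x axis), with 95% exact binomial intervals as bars. The share rises from 17.1% to 42.7% in 3T3-L1 and from 24.3% to 49.9% in C3H10T1/2.

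The next comparison asked where peaks lay relative to genes. Most lay far from gene boundaries in both lines. Within 1 kb of a boundary lay 85 of the 1557 C3H10T1/2 peaks (5.46%, 4.38 to 6.71), which was 1.797 times the 3.04% of random placement (p = 0.0001 for n = 1557, the smallest these draws can give). Within 5 kb the C3H10T1/2 share was 1.14 times random (p = 0.0216 for n = 1557). In 3T3-L1, 95 of 2445 peaks lay within 1 kb (3.89%, 3.15 to 4.73), or 1.30 times the random 2.99% (p = 0.0067 for n = 2445). The excess in 3T3-L1 did not pass the test without dense blocks (3.37%, 1.10 times random, p = 0.232 for n = 1990) and was absent within 5 kb (0.998 times random). Gene bodies held 37.7% of 3T3-L1 peaks (35.7 to 39.6) against 41.1% of random positions (n = 2445, p = 0.0002 for a lower share), and 43.8% of C3H10T1/2 peaks (41.3 to 46.3) against 40.9% (n = 1557, p = 0.012 for a higher share). The higher share in C3H10T1/2 did not pass 0.025 without dense blocks (1.06 times random, p = 0.0276 for n = 1532) or with the wider peaks alone (1.04 times), and was absent when each peak was moved by only 10 to 100 kb to draw chance (0.991 times). The lower share in 3T3-L1 did not pass it without dense blocks (0.953 times random, p = 0.0433 for n = 1990) but did with those small moves, both with the blocks (0.919 times, p = 0.0001 for n = 2445, the smallest these draws can give) and without them (0.940 times, p = 0.0006 for n = 1990).

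Sites found in both lines lay near gene boundaries more often than sites of one line. Of the 548 shared peaks of 3T3-L1, 7.30% (5.27 to 9.81) lay within 1 kb of a boundary, against 2.90% (2.19 to 3.76) of the 1897 peaks of 3T3-L1 alone (two-sided Fisher's exact p = 1.3e-05). In C3H10T1/2 the shares were 7.41% and 4.42% (exact p = 0.0186). Peaks of 3T3-L1 alone lay there less often than the 4.42% (3.25 to 5.88) of the 1017 peaks of C3H10T1/2 alone, with a difference of -1.53 percentage points (exact p = 0.0331). Without dense blocks it was -2.65 points (1.86% against 4.51%, exact p = 0.000211), and it did not pass the test within 5 kb (p = 0.131) or among peaks of at least the median width (p = 0.242).

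The lists of genes tied to the lineages these cells can enter gave the following picture. Wnt signalling genes stood near 3T3-L1 peaks more often than random genes did, with a peak within 100 kb of 13 of 34 genes against 5.15 expected (2.53 times, adjusted permutation p = 0.0288). Among the 13 were the secreted Wnt antagonists Sfrp1, Sfrp2 and Sfrp4 and the Dickkopf family genes Dkk2 and Dkk3. Also among them were the R-spondin receptor gene Lgr4, the receptor genes Fzd6, Fzd7 and Ryk and the feedback inhibitor Axin2. So were the nuclear effectors Tcf7l1 and Tcf7l2. In C3H10T1/2 it was 9 of 34 genes (adjusted permutation p = 0.0987), and the difference between the lines did not pass its test (adjusted Fisher p = 0.905). The Wnt call in 3T3-L1 ended in a window of 10 kb (2 genes, 2.66 times random, adjusted permutation p = 0.857), with each peak given to its nearest gene (8 genes, 2.40 times, 0.064), inside genes or within 10 kb of them (5 genes, 2.73 times, 0.187) and with the wider peaks alone (5 genes, 1.75 times, 0.687). It held without dense blocks (2.53 times, adjusted permutation p = 0.0128) and with neighbouring genes counted once (2.65 times, 0.016). Random lists matched on gene length, on density and length or on window length also kept it (adjusted permutation p = 0.0192, 0.032 and 0.0224).

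Extracellular matrix genes had peaks within 100 kb at 13 of 40 genes in 3T3-L1 against 5.96 expected (2.18 times, adjusted permutation p = 0.0427) and at 12 of 40 in C3H10T1/2 against 4.99 (2.41 times, adjusted p = 0.0416). By nearest gene it was 11 of 40 (2.75 times) and 10 of 40 (3.18 times), with an adjusted permutation p of 0.0088 for each. Postn, Timp3, Dcn, Lum, Adamts5, Lox and Col5a1 had a peak within 100 kb in both lines. Several of these genes are neighbours that a single peak reaches, such as Dcn and Lum. With neighbouring genes of the list counted once the counts were 10 of 34 (1.98 times, adjusted permutation p = 0.157) and 8 of 34 (1.90 times, 0.276), and with random lists matched on gene length both adjusted p-values were 0.0592 (2.03 and 2.13 times). With the wider peaks of each list alone it was 12 of 40 genes in 3T3-L1 (3.63 times random, adjusted permutation p = 0.0064) and 3 of 40 in C3H10T1/2 (1.08 times, 0.856). The difference between the lines did not pass its test there, which was added after seeing the data (10 genes against 1 in one line alone, adjusted Fisher p = 0.249), nor with all peaks (6 against 5, adjusted p = 1). Inside the genes or within 10 kb there were peaks at Dcn alone in 3T3-L1 (1 of 40 genes against 2.11 expected) and at Col4a2 and Mmp2 in C3H10T1/2 (2 of 40 against 1.84).

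BMP and TGF-beta signalling genes, which direct precursor cells toward bone, cartilage and fat, passed the test for C3H10T1/2 in some windows. Of the 37 genes, 10 had a peak within 100 kb against 4.80 expected (adjusted permutation p = 0.0939), 11 were the nearest gene of a peak against 3.45 (adjusted p = 0.0088) and 6 had one within 10 kb of a boundary against 0.717 (8.37 times, adjusted p = 0.0096). Within 100 kb the adjusted permutation p was also 0.113 with random lists matched on gene length and 0.756 with the wider peaks alone (4 genes, 1.49 times random). In a window chosen after seeing the data, inside the gene or within 10 kb of it, there were 9 genes in C3H10T1/2 against 1.91 expected (adjusted permutation p = 0.0032) and 1 in 3T3-L1 against 2.18 (adjusted p = 1). Both this window and the nearest gene count can favour long genes, and neither was tested with random lists matched on gene length. The 9 genes were the ligand gene Bmp6, the receptor gene Bmpr1a, the signal transducers Smad3 and Smad5, the inhibitory Smad7, the BMP target genes Id1 and Id3, and Ltbp1 and Ltbp2, whose products hold latent TGF-beta in the matrix or are related to such proteins. Ltbp1 alone also had a 3T3-L1 peak, at a site shared by the lines (chromosome 17, 75263670 to 75263830 in 3T3-L1). So 8 genes of the list had a peak in C3H10T1/2 alone and 0 in 3T3-L1 alone, while other genes divided 416 to 493 (two-sided Fisher's exact test, adjusted p = 0.0323). In the 100 kb window that difference was 8 against 3 genes (adjusted Fisher p = 0.589), and within 10 kb of a boundary it was 6 against 0 (adjusted p = 0.158). Id3 (chromosome 4, 136143822 to 136145392) had its peak 3.45 kb below its lower coordinate, at 136140287 to 136140461, and the nearest 3T3-L1 peak was 1540 kb away. Id1 (chromosome 2, 152736251 to 152737410) had a C3H10T1/2 peak 4.2 kb above its higher coordinate. Within 100 kb of Id1 there were also 2 peaks of 3T3-L1, the nearest a shared one 55.3 kb from the gene. The Smad5 peak at 56703863 to 56704065 on chromosome 13 lay inside the gene, 954 bp from its lower boundary, and the Ltbp2 peak lay 486 bp beyond its higher boundary.

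Adipogenesis genes included Pparg and Cebpa, the main drivers of fat cell formation, with sites in 3T3-L1, but the list did not pass the adjusted test in that window. Inside the gene or within 10 kb, 5 of the 30 genes had a 3T3-L1 peak against 1.35 expected (permutation p = 0.0096, adjusted p = 0.154) and 2 had a C3H10T1/2 peak against 1.27 (adjusted p = 0.726). The difference between the lines did not pass its test (adjusted Fisher p = 1). By nearest gene alone the 3T3-L1 count was 8 of 30 against 2.41 (adjusted permutation p = 0.0088), and within 100 kb it was 7 of 30 in each line (adjusted p = 0.333 in 3T3-L1 and 0.295 in C3H10T1/2). Pparg, which encodes a nuclear receptor (chromosome 6, 115360879 to 115490404), had 2 peaks of 3T3-L1 in its body, the nearer to a boundary at 115463053 to 115463218, and 0 of C3H10T1/2, whose nearest peak lay 43.9 kb below the gene. Cebpa, a partner of Pparg in that program (chromosome 7, 35119293 to 35121928), had a 3T3-L1 peak 2.41 kb above its higher coordinate, at 35124298 to 35124379. Retsat, the retinol saturase gene, had a 3T3-L1 peak inside it at 72601870 to 72602012 on chromosome 6, and Ebf2, a factor of brown fat precursors, had one at 67242156 to 67242438 on chromosome 14. None of these peaks was shared. Ebf1 had a shared peak in its body, at 44951620 to 44951707 on chromosome 11 in 3T3-L1, and Rxra, whose product pairs with that of Pparg, had 2 peaks of C3H10T1/2 alone inside it or within 10 kb.

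For the other lineages no list passed the adjusted test. Osteogenesis genes had a peak within 100 kb at 4 of 24 genes in 3T3-L1 and 5 of 24 in C3H10T1/2, chondrogenesis genes at 2 and 4 of 16 and myogenesis genes at 3 and 2 of 16, with folds of 0.812 to 2.03 and adjusted p-values of 0.333 or more. By nearest gene the osteogenesis counts were higher, at 6 of 24 in 3T3-L1 (2.96 times random, adjusted permutation p = 0.064) and 5 of 24 in C3H10T1/2 (3.14 times, 0.066). Runx2, the transcription factor that commits cells to bone, had 1 peak in its body in each line, at 44667600 to 44667732 in 3T3-L1 and 44588027 to 44588192 in C3H10T1/2 on chromosome 17, and these did not overlap. Sp7, a bone factor that acts after Runx2, had no peak within 100 kb in either line. Mesenchymal precursor markers had peaks within 100 kb at 9 of 26 genes in 3T3-L1 (adjusted permutation p = 0.0755) and 5 of 26 in C3H10T1/2 (0.458). Prrx2 had a 3T3-L1 peak 4.44 kb from the gene and Prrx1 a C3H10T1/2 peak 4.61 kb from the gene.

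Gata2 itself (chromosome 6, 88193891 to 88207032) had no peak within 100 kb in either line, the nearest lying 122 kb away in 3T3-L1 and 718 kb away in C3H10T1/2. Gata1, Gata4 and Gata6 had none within 100 kb in either line. Gata3 had a 3T3-L1 peak 9.68 kb below its lower coordinate and Gata5 one 75.9 kb away. Of the cofactors, Zfpm1 had none, and Zfpm2 had 2 peaks of 3T3-L1 in its body. Trps1, an atypical GATA protein that represses transcription (chromosome 15, 50654757 to 50890631), had 3 peaks of 3T3-L1 and 2 of C3H10T1/2 in its body, with 1 shared site. Over the list, 3 of 15 genes in 3T3-L1 (adjusted permutation p = 0.597) and 1 of 15 in C3H10T1/2 (0.939) had a peak within 100 kb. The 3T3-L1 count was 4.44 times random inside genes or within 10 kb (3 genes, adjusted permutation p = 0.187) and 3.12 times by nearest gene (4 genes, 0.0787). Known GATA2 targets of blood and endothelial cells had a peak within 100 kb at 3 and 2 of 22 genes (adjusted permutation p = 0.883 and 0.924). Their counts by nearest gene were 6 in 3T3-L1 (2.49 times random, adjusted permutation p = 0.0701) and 5 in C3H10T1/2 (2.73 times, 0.0787), and inside genes or within 10 kb 4 (3.34 times, 0.187) and 2 (0.705). The endothelial adhesion gene Pecam1 had a shared peak in its body, and the blood stem cell factor Runx1 had 1 peak of 3T3-L1 and 4 of C3H10T1/2, with 1 shared site.

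Among the remaining lists, Notch and Hedgehog genes had a peak within 100 kb at 5 of 24 genes in 3T3-L1 and 4 of 24 in C3H10T1/2 (adjusted permutation p = 0.532 and 0.587). Notch1 had a shared peak in its body, and Hes1, a target of Notch signalling, had a shared peak 664 bp above its higher boundary, at 30068362 to 30068557 on chromosome 16 in 3T3-L1. Actin cytoskeleton and YAP target genes had 7 and 5 of 32 (0.333 and 0.587), with shared peaks in the body of the non-muscle myosin gene Myh9. Of the tropomyosin genes, Tpm4 had a 3T3-L1 peak 2.22 kb below its lower coordinate and Tpm1 a C3H10T1/2 peak in its body, neither of them shared. AP-1 and immediate early genes had 5 and 6 of 25 (0.532 and 0.304), with a shared peak in Mafk. Inflammatory mediators had 8 and 3 of 23 (0.0755 and 0.809), several of them in the chemokine clusters, and the shared peak nearest to one of these genes lay 942 bp below Cxcl5, at 90758282 to 90758429 in 3T3-L1. Lgr4 and Dkk3 of the Wnt list also held shared peaks, with 2 such sites in Lgr4. As for the control lists, ribosomal protein genes had 4 and 1 of 49 genes against 6.24 and 5.795 expected (0.939 and 0.998) and synapse genes 3 and 2 of 30 against 4.49 and 3.85 (0.939 in both lines). These one-sided tests do not look for low counts, and the 1 ribosomal protein gene of C3H10T1/2 lay below the 2 to 10 genes that 95% of random lists gave (0.173 times random).

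**Figure D3:**
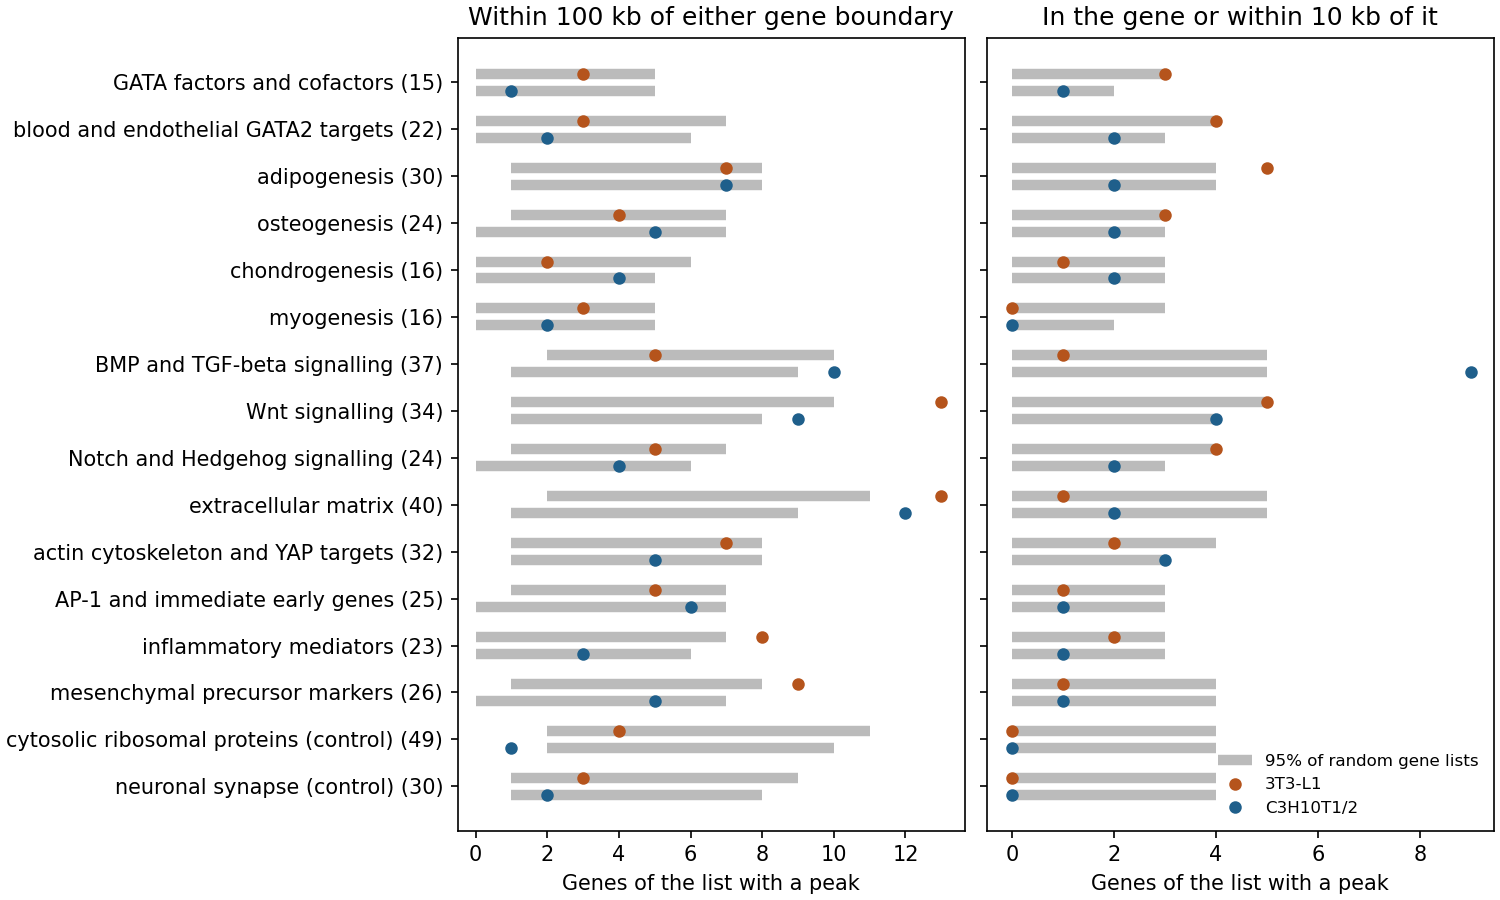
Number of genes of each fixed list with a GATA2 peak within 100 kb of either gene boundary (left) or in the gene or within 10 kb of it (right), in 3T3-L1 and C3H10T1/2 (points), with the range of 95% of random gene lists as grey bars and the list's size in brackets. In the right panel BMP and TGF-beta signalling in C3H10T1/2, with 9 genes, lies furthest beyond its grey bar, and in the left panel Wnt signalling in 3T3-L1 reaches 13 of 34 genes.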

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

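Of the tests in this part, those for extra copies, for a collapsed reference sequence, for weak sites and for unequal list sizes were set up after their results had been seen, and those for peak clumping and for chance misses before.

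The share of peaks on chromosome 10 differed between the lines by 17.2 percentage points, the widest gap of the 20 chromosomes. The gap came from 3 blocks of 444 closely spaced 3T3-L1 peaks around Mdm2, at Lyz2 and between Acss3 and Lin7a, which ended sharply, with 0 peaks in the 100 kb beyond the outer edges. A reference sequence that is repeated or collapsed would crowd both lists if these were called and cleaned alike, which is not known. Only on that condition would the 0 peaks of C3H10T1/2 in these blocks, with an upper 95% limit of 3.69, argue against it. The other dense blocks do not settle whether it holds, and their causes were not tested. That on chromosome 17 held 10 peaks of 3T3-L1 and 5 of C3H10T1/2, and that in Sfi1 held 1 of 3T3-L1 and 20 of C3H10T1/2. Extra copies of the chromosome 10 segments in 3T3-L1 DNA, which may have lifted background reads over the peak threshold, stay open and untested by sharing, since 0 of the 444 peaks could be shared where C3H10T1/2 has none. Dense binding special to 3T3-L1 stays open too: peak centres clumped more than random placement gave (variance over mean per 5 kb of 1.63 against 0.72, n = 376 peaks, p = 0.0005, the smallest 2000 random placements can give), and it cannot be told apart from uneven coverage of amplified DNA without the input reads. The prediction for dense binding also asked that block peaks be shared at least as often as elsewhere, where 27.4% of 3T3-L1 peaks were shared. With no C3H10T1/2 peak in the blocks this part could not be met, so it decides nothing.

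Most peaks were in one list alone, and the candidate explanation tested is that weak sites were called in one line and missed in the other. It predicted that wider peaks are shared more, and the widest of 4 width classes was shared at 34.7% in 3T3-L1 against 13.1% in the narrowest, and at 50.1% against 23.6% in C3H10T1/2. If narrow peaks are weak ones, which could not be checked without a score, weak sites could account for part of the unshared peaks. The widest C3H10T1/2 class was still 49.9% unshared, so binding that differs between the lines stays open as well, as untested.

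Genes of BMP and TGF-beta signalling divided between the lines otherwise than other genes: 8 had a peak inside or within 10 kb in C3H10T1/2 alone and 0 in 3T3-L1 alone. The unequal size of the lists would favour the longer 3T3-L1 list (other genes divided 416 to 493). The BMP and TGF-beta genes leaned to C3H10T1/2 in each window, the opposite of what list size alone would favour. The windows share genes and peaks, and the gene list was flagged for this lean, so they are not separate evidence. In the windows fixed before the data were examined these genes divided 6 to 0 within 10 kb of a boundary (adjusted Fisher p = 0.158). That was the test of list size, which needed an adjusted p under 0.05 to count against it, so it cannot tell. Within 100 kb they divided 8 to 3 (adjusted Fisher p = 0.589), so chance is not excluded in these windows. Sites missed by chance in 3T3-L1 stay open: 8 of the 9 C3H10T1/2 peaks at these genes were unshared against 65.2% of the other peaks, a difference that so few peaks do not separate from chance (one-sided binomial p = 0.123). The median width of these 9 peaks was 175 bp, against 184 bp in the whole list. It was 174 bp for unshared and 205 bp for shared C3H10T1/2 peaks, so the 9 peaks were about as wide as unshared ones. A difference in GATA2 binding between the lines at these genes may exist as a hypothesis, and it rests on a window chosen after seeing the data (adjusted Fisher p = 0.0323).

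Outside dense blocks, 4 of the 20 chromosomes held different shares of the lists after adjustment. Relative to C3H10T1/2, the 3T3-L1 share differed by -2.83 percentage points on chromosome 1 (adjusted Fisher p = 0.0112), by -2.19 on chromosome 4 (0.0306) and by 2.16 on chromosome 5 (0.0306). On chromosome X the difference was 2.04 points, with 60 peaks of 3T3-L1 and 15 of C3H10T1/2 (adjusted Fisher p = 0.00054). The cause of these differences was not tested, and the copy number of the chromosomes in either line was not measured here.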

How the results depend on the processing

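The sharing of peaks stayed above random placement in all 10 alternative values (18.2% to 27.0% of 3T3-L1 peaks and 28.5% to 36.2% of C3H10T1/2 peaks), and shared peaks stayed nearer gene boundaries than unshared ones under every alternative run. The settings without dense blocks, with small moves of peaks, inside genes or within 10 kb, with matching on density or window and with neighbours counted once were chosen after seeing the data. Other results moved. The 3T3-L1 excess within 1 kb of a boundary was 1.10 times random without dense blocks, 1.21 there with small moves and 0.998 within 5 kb, where that of C3H10T1/2 was 1.14. In gene bodies the fold was 0.953 for 3T3-L1 and 1.06 for C3H10T1/2 without dense blocks, and for C3H10T1/2 1.04 with wider peaks, 0.991 with small moves and 0.979 with these and no dense blocks. Peaks of 3T3-L1 alone against those of C3H10T1/2 alone gave -1.91 points within 5 kb and -1.24 with wider peaks, which are 1223 and 781 in number. In 3T3-L1, 2 lists were called in the main setting, 0 within 10 kb, 0 inside genes or within 10 kb, 0 there without dense blocks, and 1 each when matched on gene length, with wider peaks, matched on density and length, matched on window length and with neighbours counted once. In C3H10T1/2, 1 list was called in the main setting, 2 by nearest gene, and 0 in each of the latter 5 settings. Which list was called also changed. In C3H10T1/2 it was extracellular matrix in the main setting, but BMP and TGF-beta signalling within 10 kb and inside genes or within 10 kb. In 3T3-L1 the single list was extracellular matrix with wider peaks and Wnt signalling in the other settings that called 1. By nearest gene the 3T3-L1 calls were adipogenesis and extracellular matrix. The extracellular matrix fold in 3T3-L1 fell below 1 inside genes or within 10 kb, to 0.473, and to 0.484 there without dense blocks. The cause was not tested for any of these, except that wider peaks are a smaller list. The motif and score settings were not run, since no genome sequence or score was used here. No paired analysis was possible because each line has a single list that carries no replicate numbers, and no replicate could be left out for the same reason. Unknown read depth limits every statement on sites absent from one list.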

Other observations

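Several genes outside the fixed rule, chosen after their values were seen, had sites in or within 10 kb of them. In the Wnt list these were the effector genes Tcf7l1 and Tcf7l2 in C3H10T1/2 and the Dickkopf family gene Dkk2 in 3T3-L1. Rbpj, the DNA-binding effector of Notch, and Gli3, an effector of Hedgehog signalling, had 3T3-L1 peaks. The cartilage genes Sox6 and Col11a1 had C3H10T1/2 peaks and Sox5 a 3T3-L1 peak. Phex, which acts in bone mineralisation, had a 3T3-L1 peak, and Ank, whose product exports pyrophosphate, had a C3H10T1/2 peak. Nfkb1 had a 3T3-L1 peak and Vcl, which encodes the adhesion protein vinculin, a C3H10T1/2 peak. None of the osteogenesis, chondrogenesis, Wnt, Notch and Hedgehog, inflammatory mediator or actin lists passed the adjusted test in that window in either line.

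The 13 peaks of 3T3-L1 around Cwc22 on chromosome 2 resemble the blocks of chromosome 10 in having 0 C3H10T1/2 peaks within 100 kb, the nearest lying 1620 kb from the gene. The segment that holds Cwc22 is known to vary in copy number between mouse strains, and amplification of Mdm2 in 3T3-L1 cells is known from earlier work; neither was used in the tests. The copy number of either region was not measured here.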
